A study of Mus musculus with 12 samples.

How the data were processed

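Genomic DNA from 12 mouse liver tumours (hepatocellular carcinoma, HCC) was hybridised to 12 two-colour Agilent arrays for comparative genomic hybridisation, an assay in which the ratio of 2 dyes at each probe follows the ratio of DNA copies in 2 samples. Per the labels, tumour DNA carried Cy5, aliquots of 1 normal liver DNA carried Cy3 on every array, no dyes were swapped, and all animals were of a C57BL6/CBA background and aged 8 months. The mice carried an inactivation of PR-SET7, a histone H4 lysine 20 methyltransferase encoded by Kmt5a, in hepatocytes. The submitters' processing notes list Agilent Feature Extraction 10.7.3.1. Scanner files, spot intensities and any smoothing or filtering steps were not used here.

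The deposited table held 173119 rows and 12 columns, 1 per tumour. The authors' deposited values were read as log2 ratios. Their sizes reach 9.17, which base 10 would place beyond the range of a scanner. Base 2 and natural logs are not told apart by the sources used here, and natural logs would multiply every log2 value given here by 1.44. The direction of the ratio is not given either. It was taken as tumour over reference, which is likely because the labels put the tumour in Cy5 and Agilent's software reports Cy5 over Cy3. Gain and loss are used in that sense, and under the opposite reading each gain would be a loss of the same size. The deposited column medians lay between -0.026 and 0.178. The most common level of the 101-probe running median lay between -0.005 and 0.02 on each array, so the deposited columns appear to be centred near that level and not on the median. Each array was centred here on its median, as fixed before the data were examined.

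A total of 8204 rows had no value on any array, of which 2814 were control rows, and no row was filled on some arrays only. The other 164915 probes were tested. Gene names and genomic positions of the probes were not used here: of every 1000th probe ID looked up, 0 occurred in the mouse gene table. The planned tests of Kmt5a, of the 10 fixed gene lists (tumour suppressors, oncogenes, cell cycle, DNA damage response, replication origin, hepatocyte identity, progenitor, germline copy-number variant, antigen receptor and Y-linked genes) and of the sex chromosomes were therefore not analysed here, and the planned gene and chromosome tests were run on probes and on windows of probes. X and Y probes could not be left out of the centring or the counts.

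The 162551 probes of the main series were placed in the order of their ID numbers. This order was checked on the values. The correlation between neighbouring probes lay between 0.0715 and 0.495 on the 12 arrays, against -0.0021 to 0.00522 after shuffling. The numbers fall into 3 runs of 38160, 84368 and 40023 probes, parted at the 2 largest gaps. After alignment by dynamic time warping, the profiles of any 2 runs correlated with a median r over arrays of 0.977 to 0.98, against 0.525 to 0.553 with a run reversed, so the 3 runs were taken as 3 passes over 1 order of loci. Places are given as a percent of the probes of a run. The other series of 2364 probes showed no such order (neighbour r of -0.0544 to 0.00806) and entered only the test per probe.

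For single probes, limma 3.58.1 in R 4.3.3 was fitted with an intercept only (lmFit and eBayes), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 and a mean of at least 0.2 in size. For windows of 500 probes, the 12 tumour means were tested against 0 by an exact two-sided sign-flip test with Benjamini-Hochberg adjustment over 325 windows; the smallest p it can give is 0.000488. At least 3 adjacent called windows of 1 direction made a block. The closest block in another run was the block with the smallest mean absolute difference in tumour values. A region was named where a block of run 1 had a closest block in both other runs whose tumour values correlated at 0.9 or more with its own. Each tumour was segmented by penalised least squares (penalty of 4 times the log of the number of probes times the noise variance). Segments of at least 5 probes with a mean of 0.2 or more were called gained, and of -0.2 or less lost. A gain or loss was called recurrent at or above the 95th percentile of the highest number of tumours sharing a probe in 1000 genomes whose tumours were each rotated at random. Similarity between arrays is Pearson's r over probes or windows, which are not independent replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 was used.

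The rule for named items was fixed before the data were examined: the highest and lowest means among called genes with 1 sign in at least 10 of 12 tumours, and the 5 most gained and 5 most lost segments. With no gene names, the 2 highest and the 2 lowest probes stand for the genes. The steps were tested on simulated data. With 164915 probes simulated, the probe test against 0 recovered 85% of 100 probes changed by 0.3 and 99% of 100 changed by 0.6, with 2 false calls. With 162551 probes simulated for 1 array, segmentation recovered 20 of 20 segments of 100 probes shifted by 0.3, and 20 of 20 segments of 20 probes shifted by 0.6. The sign-flip test recovered 40 of 40 windows changed by 0.1 among 325. Real windows differed in their spread between tumours, and some arrays had nearly the same profile, so this rate need not hold for them. No planted segment was shorter than 20 probes. The simulation therefore cannot show whether shorter calls, or recurrent gains and losses that rest on them, are sound.

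The labels name 1 group of 12 replicates and no control array, so the ratio against 0 is the test. It leaves out the spread of the reference, and copy-number variants of the reference animal or a dye bias of a probe enter every array alike. The labels do not say which tumours came from separate animals, so p-values measure only the spread between these 12 samples. The number of arrays limits the precision, and the noise SD of a single probe, from successive differences, lay between 0.143 and 0.227. Alternatives covered the centring, size thresholds, limma's treat and its trend and robust options, each tumour left out, the log base, segmentation settings, removal of the component common to all arrays, and the similarity measure.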

Results

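Copy-number ratios were measured in 12 liver tumours of mice whose hepatocytes lack PR-SET7, the enzyme that places the first methyl group on lysine 20 of histone H4. The series was set up to study the function of PR-SET7 in liver development, hepatocyte proliferation and regeneration, and each tumour (HCC replicates 1 to 12, tumours 1 to 12 here) was compared with the same normal liver DNA. The comparison the design gives is tumour against normal liver, at 164915 probes. Values are median-centred log2 ratios, likely of tumour over reference, and places are given as a percent of the probes of each of the 3 runs of probe numbers.

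At a segment threshold of 0.2, the tumours ranged from nearly flat to broadly altered. Tumour 10 had 16.9% of its probes in gained segments, tumour 5 had 16.7%, tumour 6 had 16.1%, tumour 9 had 15.7% and tumour 8 had 15.6%. Tumours 7, 12 and 2 had 6.65%, 5.92% and 5.24% gained, and tumours 3, 1, 4 and 11 had 2.14%, 0.985%, 0.826% and 0.515%. Losses were widest in tumour 2, at 14.9% of probes, and in tumour 9, at 10.6%, followed by tumour 3 at 4.51%, tumour 6 at 2.47% and tumour 10 at 2.06%. The other 7 tumours had between 0.204% and 1.05% of probes lost. Tumours 4 and 11 had 0 gained and 0 lost regions of 100 probes or more, and tumour 8 had 21 such gained regions and 0 lost. Over the 12 tumours the median share was 6.28% gained (SD 6.99, n = 12) and 0.979% lost (SD 4.7, n = 12). Each share belongs to 1 array, so no test was made between tumours. A share past a fixed threshold also depends on the amplitude of a profile. The windows of tumours 9 and 12 correlated at r = 0.981, with a slope of 0.759 for tumour 12 on tumour 9. Their lost shares were 10.6% and 0.482%, and their gained shares 15.7% and 5.92%. The shares therefore do not rank the tumours by how much of the genome is altered.

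The order of the tumours by gains and by losses depends on the processing. Centring on the median sets the balance of gains and losses within a tumour. The deposited medians of tumours 5 and 6 lay at 0.133 and 0.178, and with the centre at the mode of the running median their gained shares were 31.5% and 49.8%. With that centre the gained shares of tumours 10 and 12 were 6.65% and 0.582%, and losses were 26.3% in tumour 9, 16.4% in tumour 10 and 7.5% in tumour 2. With the threshold of a segment at 0.1 in place of 0.2, tumours 6 and 2 had the widest gains, at 31.2% and 25%, and tumours 6 and 5 the widest losses, at 37.8% and 35.6%. At 0.3, tumours 6 and 5 had gained shares of 7.96% and 6.76%, and tumours 8, 9 and 10 had 1.36%, 0.702% and 0.624%. With the component common to all 12 arrays removed, the gained shares of tumours 5 and 6 fell to 9.25% and 8.19% and their lost shares rose from 1.05% and 2.47% to 6.2% and 6.1%, the gained shares of tumours 8, 9 and 10 were 2.45%, 0.113% and 0.0794%, and the lost shares of tumours 2 and 9 were 0.133% and 0.466%.

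**Figure D1:**
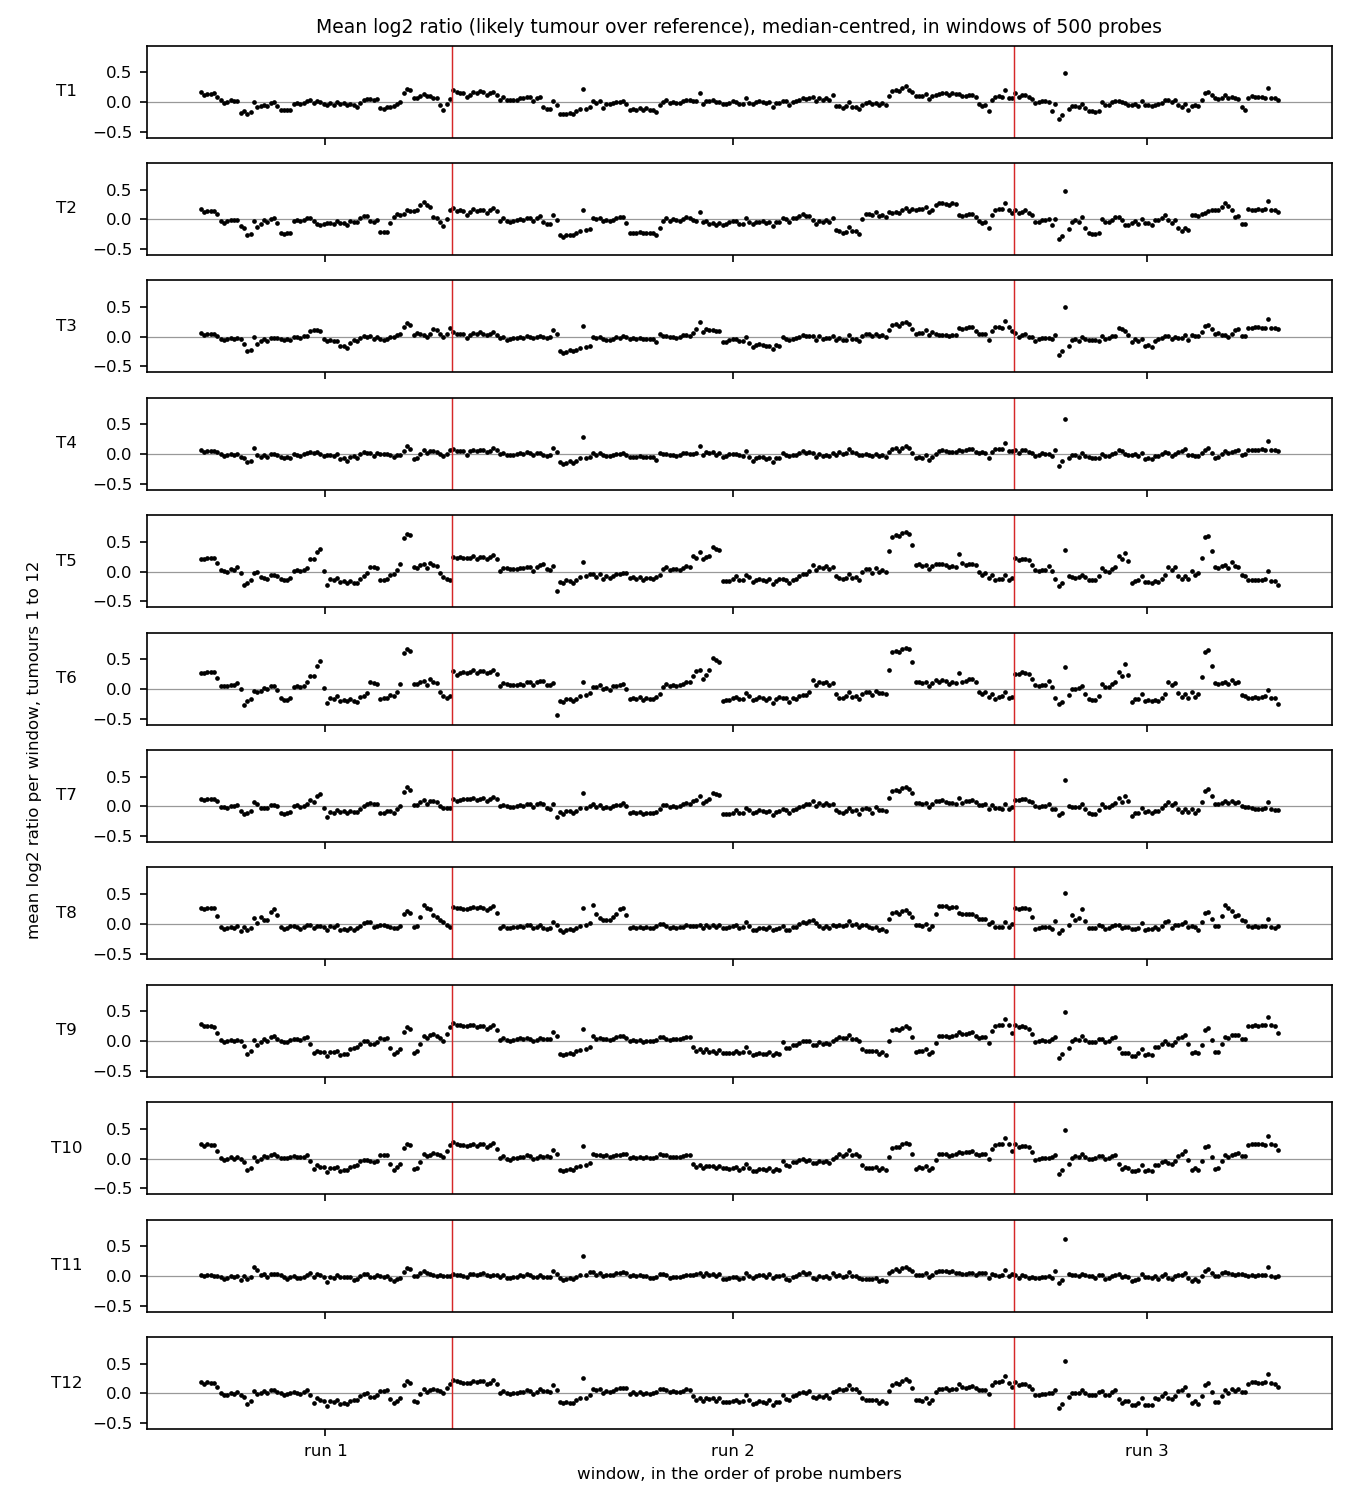
Mean log2 ratio (y axis, 1 panel per tumour) in 325 windows of 500 probes, in the order of probe numbers (x axis, red lines part the 3 runs); each point is 1 window. The same profile recurs in the 3 runs of a tumour, and tumours 4 and 11 lie closest to 0.

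Among gained segments of 100 probes or more, tumour 6 had the 4 largest means. A segment of 118 probes at 90.1 to 90.2% of run 2 had a mean of 0.73, and 2 segments between 80.6 and 82.1% of run 2, of 714 and 548 probes, had means of 0.68 each. A segment of 677 probes at 82 to 83.8% of run 1 had a mean of 0.66. Tumour 5 followed with 0.65 over the same 548 probes of run 2. Losses of 100 probes or more were deepest in tumour 6 as well, at -0.48 over 145 probes at 15.3 to 15.7% of run 3 and at -0.48 over 164 probes at 17.1 to 17.6% of run 1. In run 2 the deepest, at -0.46, covered 363 probes from 18.3 to 18.7%. The 145 probes of run 3 had a mean of -0.38 in tumour 5. Among segments of any length, the 5 most gained had means of 6.4 to 6.77 and lay at 23.3% of run 2 and at 19.6 to 19.7% of run 3. The 5 most lost covered 5 probes each. Of these, 1 at 77.1% of run 1 was shared by tumours 5, 6 and 7, with means of -2.66, -2.8 and -2.65.

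**Figure D2:**
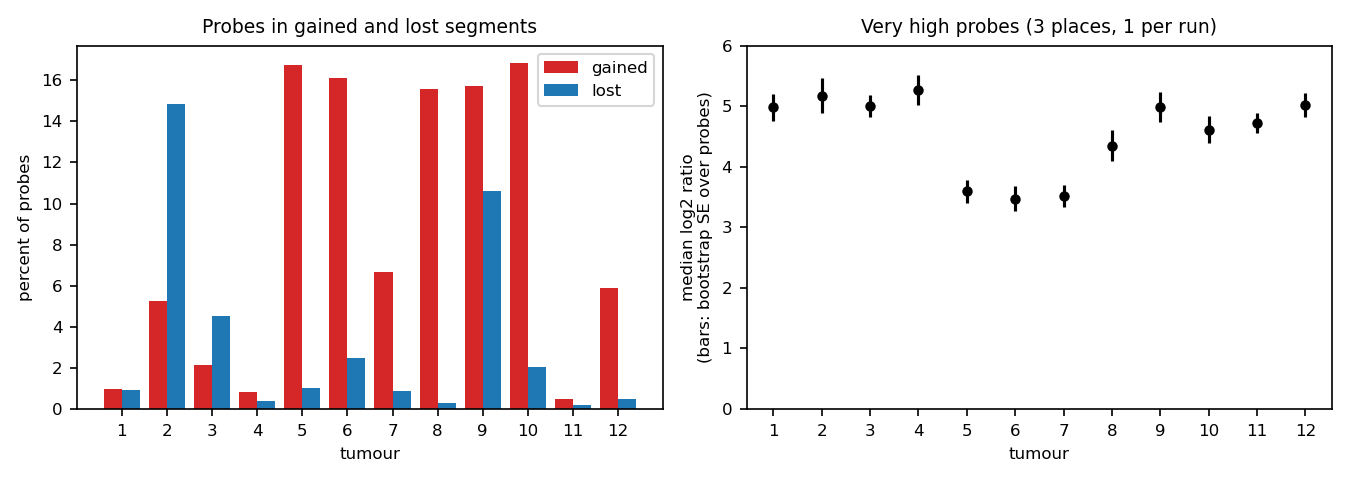
Left, percent of probes in gained and lost segments (y axis) per tumour (x axis); the gained share ran from 0.515% to 16.9%. Right, median log2 ratio of the 123 very high probes per tumour, with bars for the bootstrap SE over probes; tumours 5, 6 and 7 lay between 3.47 and 3.59 and the other tumours between 4.34 and 5.26.

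Many parts of the genome departed from the reference in 1 direction in most tumours. Of 325 windows, 88 were higher and 86 were lower than 0 (27.1% and 26.5%; exact sign-flip test, adjusted p under 0.05). In 57 windows all 12 tumours were higher and in 40 all 12 were lower. For 12 independent arrays, chance gives 0.0488% of windows for all tumours of 1 sign. These arrays share 1 reference and some have nearly the same profile, so that figure is too low for them. The split depends on the centring: with the values as deposited 130 windows were higher and 47 lower, so that 73.4% of the called windows were higher, against 50.6% after median centring. Averaging tumours 5, 6 and 7 and tumours 9, 10 and 12, whose window profiles correlated at 0.9 or more, left 8 values, with 68 windows higher and 56 lower.

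Called windows formed 5 regions that were seen in each of the 3 runs. The largest shift was a gain in region 4, at 79.9 to 83.9% of run 1, 77.6 to 82.4% of run 2 and 71.2 to 75% of run 3, covering 7000 probes. Its mean log2 ratio was 0.23 ± 0.168 (SD, n = 12), a ratio of 1.17, and it was higher in 12 of 12 tumours (exact sign-flip p = 0.000488, the smallest the test can give; adjusted p = 0.00061 over 5 regions). Tumours 6 and 5 reached 0.591 and 0.56 there, tumour 7 had 0.264, and the other 9 tumours lay between 0.081 and 0.187. Without tumour 6 the mean was 0.197, the lowest of the means with 1 tumour left out.

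Region 1, the first 7.86% of run 1, 8.3% of run 2 and 7.5% of run 3, held 13000 probes and was higher in 12 of 12 tumours, with a mean of 0.151 ± 0.0871 (SD, n = 12; exact sign-flip adjusted p = 0.00061). Tumours 6, 8, 9, 10 and 5 had between 0.212 and 0.266 in it, and tumours 11, 3 and 4 had 0.0082, 0.0365 and 0.0531. Region 5, at 86.5 to 94.3% of run 1, was higher in 12 of 12 tumours by 0.0972 ± 0.0498 (SD, n = 12; exact sign-flip adjusted p = 0.00061), from 0.0459 in tumour 4 to 0.212 in tumour 8.

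Among these regions 2 were lower than 0, with means smaller in size than the 0.2 used to call a lost segment. Region 3 lay at 48.5 to 64.2% of run 1, 48 to 52.2% of run 2 and 48.7 to 56.2% of run 3. Its extent thus differed between the runs. It had a mean of -0.0975 ± 0.0559 (SD, n = 12) and was lower in 12 of 12 tumours (exact sign-flip adjusted p = 0.00061). Tumours 6, 9 and 11 had -0.172, -0.171 and -0.0278. Region 2, from 31.4 to 36.7% of run 1, had a mean of -0.0797 ± 0.0776 (SD, n = 12) and was lower in 10 of 12 tumours (exact sign-flip adjusted p = 0.00391). It was lowest in tumour 2, at -0.236, and tumours 9 and 10 had 0.000436 and 0.011. Another 4 blocks of windows were lower in 12 of 12 tumours and deeper than region 3, but belonged to none of the 5 regions; they were singled out after their values were seen. They had means of -0.154 ± 0.0635 at 19 to 23.1% of run 2, -0.121 ± 0.0445 at 15.7 to 21% of run 1, -0.118 ± 0.0723 at 43.7 to 47.5% of run 3 and -0.11 ± 0.0663 at 52.7 to 58.7% of run 2 (SD, n = 12 each; exact sign-flip p = 0.000488 each). The tumour values of the blocks that end at 21% of run 1 and at 23.1% of run 2 correlated at r = 0.844. The other 2 lay next to the parts of region 3 in their own runs. Their tumour values correlated with those of region 3 in run 1 at 0.948 for the block of run 3 and at 0.933 for the block of run 2, so they are not taken as lower places apart from region 3. The means depend on the centring: with the values as deposited, regions 1 to 5 had 0.188, -0.0436, -0.0614, 0.266 and 0.133, and with the centre at the mode of the running median 0.178, -0.0528, -0.0705, 0.257 and 0.124. The 4 blocks, in the order given, had -0.118, -0.0848, -0.082 and -0.0735 as deposited. The 5 regions and 4 blocks were picked from windows already called, so their p-values describe the same signal as the windows. Between any 2 runs, which use different probes, the tumour values of a region differed on average by at most 0.046. The blocks were paired between runs because these values lay closest, so the small difference follows from the pairing and is no separate evidence.

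**Figure D3:**
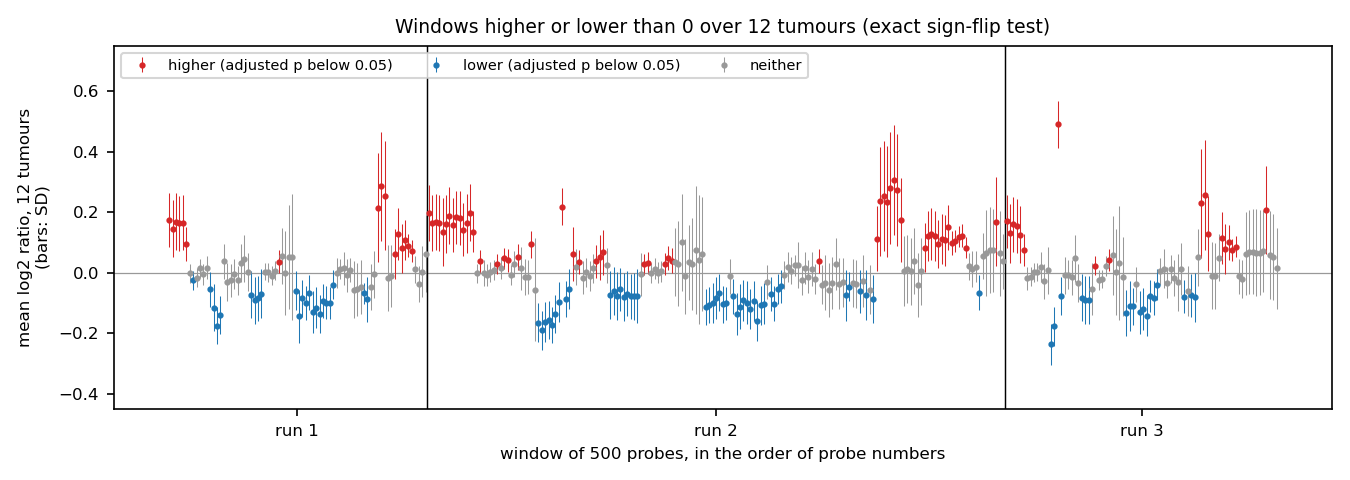
Mean log2 ratio over 12 tumours (y axis, bars are SD) per window of 500 probes in the order of probe numbers (x axis, vertical lines part the runs); red windows were higher and blue windows lower than 0 (exact sign-flip test, adjusted p under 0.05). In median-centred values 88 windows were higher and 86 lower; region 4 forms the high group near 80% of runs 1 and 2.

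Segments called in single tumours coincided more often than after random rotation. For gains the threshold was 6 tumours, and 9508 probes (5.85%) reached it. With gaps of up to 50 probes merged they lay in 94 places, of which 30 spanned 20 probes or more. Some of these held few recurrent probes, such as 15 in a span of 109 at 23 to 23.3% of run 1. The 3 runs were taken as passes over 1 order of loci, so 1 locus can count as a place in each run. The longest places lay in region 1, where 4112 probes of a stretch in run 2 were gained in up to 9 tumours (median over probes 6). In region 4, 1334 probes of run 2 and 682 of run 1 were gained in up to 12 (medians 9 and 7). The longest gained region of tumours 4 and 11 held 69 probes each, so all 12 tumours shared only short parts of these stretches. The 1334 probes include the highest single probes named below. For losses the threshold was 4 tumours, and 2871 probes (1.77%) reached it, in 102 places, of which 12 spanned 20 probes or more. A stretch of 1122 probes ending at 18.6% of run 3 and a stretch of 778 probes ending at 19.8% of run 2 were lost in up to 12 tumours. The median over their probes was only 5 and 4 tumours. Each stretch includes a single probe that was very low in all 12 tumours. In run 3 it is A_67_P12523020, named below, and in run 2 it is A_67_P05181547, with a mean of -6.14. Whether the calls shared by all 12 tumours rest on these single probes was not tested. The longest lost region held 24 probes in tumour 4, 16 in tumour 8 and 11 in tumour 11, so all 12 tumours shared only short parts of these stretches. The last 91 probes of run 3 were lost in up to 8 tumours, with medians of -0.93 in tumour 6, -0.77 in tumour 5 and -0.61 in tumour 9, against -0.028 in tumour 3 and -0.053 in tumour 8. With these like profiles averaged (tumours 5, 6 and 7, and tumours 9, 10 and 12), 1626 probes were in recurrent gains and 823 in recurrent losses. With the component common to all 12 arrays removed, the counts were 156 and 860. With segments of at least 10 probes in place of 5, recurrent gains lay in 16 places and recurrent losses in 12. Of these, 10 and 7 spanned 20 probes or more. The probes in them still numbered 8688 and 2317. Most of the places thus rest on calls of fewer than 10 probes, but most of the recurrent probes do not.

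A short stretch of probes in each run lay far above the reference in every tumour. It held 19 probes at 21 to 21.1% of run 1, 42 probes at 23.3% of run 2 and 62 probes at 19.6 to 19.7% of run 3. The medians over tumours were 4.95, 4.5 and 4.91, ratios of 30.9, 22.7 and 30.1. Over all 123 probes the mean of the tumour medians was 4.56 ± 0.669 (SD, n = 12). Tumours 6, 7 and 5 had 3.47, 3.52 and 3.59, tumour 8 had 4.34, and the other 8 tumours had between 4.61 and 5.26. The nearly flat tumours 4 and 11 had 5.26 and 4.72. A place of 7 probes at 18.2% of run 2 was higher in every tumour by 1.4 ± 0.154 (SD, n = 12), and 9 probes at 64.9% of run 2 were lower in every tumour, with a mean of -0.992 ± 0.0728 (SD, n = 12). A variant of the shared reference would give such values on every array as well.

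Per probe, 22307 probes were higher and 18379 lower (13.5% and 11.1% of those tested; limma, adjusted p under 0.05 and mean of at least 0.2 in size). With the values as deposited, 29618 were higher and 12889 lower, so that 69.7% of the calls were higher, against 54.8% after median centring. All 12 tumours were higher at 21535 probes and lower at 22969. The 2 highest probes were A_67_P08400652, with a mean of 7.68 ± 0.551 (SD, n = 12; limma adjusted p = 2.92e-17), and A_67_P08397558, with 7.55 ± 0.594 (SD, n = 12; limma adjusted p = 7.74e-17). The 2 lowest were A_67_P12523020, with -6.85 ± 0.715 (SD, n = 12; limma adjusted p = 2.67e-15), and A_67_P06513218, with -6.56 ± 0.822 (SD, n = 12; limma adjusted p = 2.94e-14). Each had the same sign in 12 of 12 tumours. Ratios of this size on every array can also come from the shared reference or from the dyes, which were not swapped.

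Some tumours had nearly the same profile. Over windows, tumours 9 and 10 correlated at r = 0.994, tumours 10 and 12 at 0.987, tumours 9 and 12 at 0.981, and tumours 5 and 6 at 0.979, and tumour 7 correlated with tumours 5 and 6 at 0.934 and 0.945. The profiles differed in amplitude: the windows of tumour 7 had a slope of 0.467 on those of tumour 6, and the windows of tumour 12 a slope of 0.759 on those of tumour 9. The differences between tumours 9 and 10 had an SD of 0.0208 over windows, 2.13 times that given by probe noise, and the other 5 such pairs had 2.44 to 11.1 times theirs. Labelling and array effects add to such differences, so they do not show whether 2 arrays hold DNA of separate tumours; the arrays were counted as 12 samples because the labels name 12. Over all 66 pairs the r of windows ranged down to 0.365, between tumours 5 and 9, with a median of 0.613. Over all probes r ranged from 0.649 to 0.914, with a median of 0.776, and 0 pairs were negative. After each probe's mean over tumours was removed, r ranged from -0.444 between tumours 7 and 12 to 0.577 between tumours 5 and 6. With each window's mean removed, r was 0.981 for tumours 9 and 10, 0.953 for 10 and 12, and 0.92 for 9 and 12. It was 0.946 for tumours 5 and 6, but 0.644 and 0.603 for tumour 7 with tumours 5 and 6. Tumours 4 and 11 reached 0.799 by this measure. Among the like pairs, removing the mean thus lowered r most for those with tumour 7.

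Single-probe values grouped the tumours too. At the 1626 most variable probes, after the running median of 51 probes and the mean of each probe were removed, tumours 1 to 4, tumours 5 to 7 and tumours 8 to 12 formed 3 sets. The 19 pairs within a set had r between 0.531 and 0.848, and the 47 pairs between sets had r between -0.557 and -0.227. Over all 162551 probes treated in the same way the sets did not part: r within sets ran from -0.152, between tumours 1 and 4, to 0.415, and r between sets from -0.472 to 0.238, between tumours 1 and 12. Without the 1626 most variable probes, r ran from -0.417 to 0.258 within sets and from -0.472 to 0.436 between sets, so the sets rest on the most variable probes. The like profiles of tumours 5, 6 and 7 and of tumours 9, 10 and 12 lay within sets. The labels do not name the animal of each tumour, and every p-value given here treats the 12 arrays as separate samples.

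**Figure D4:**
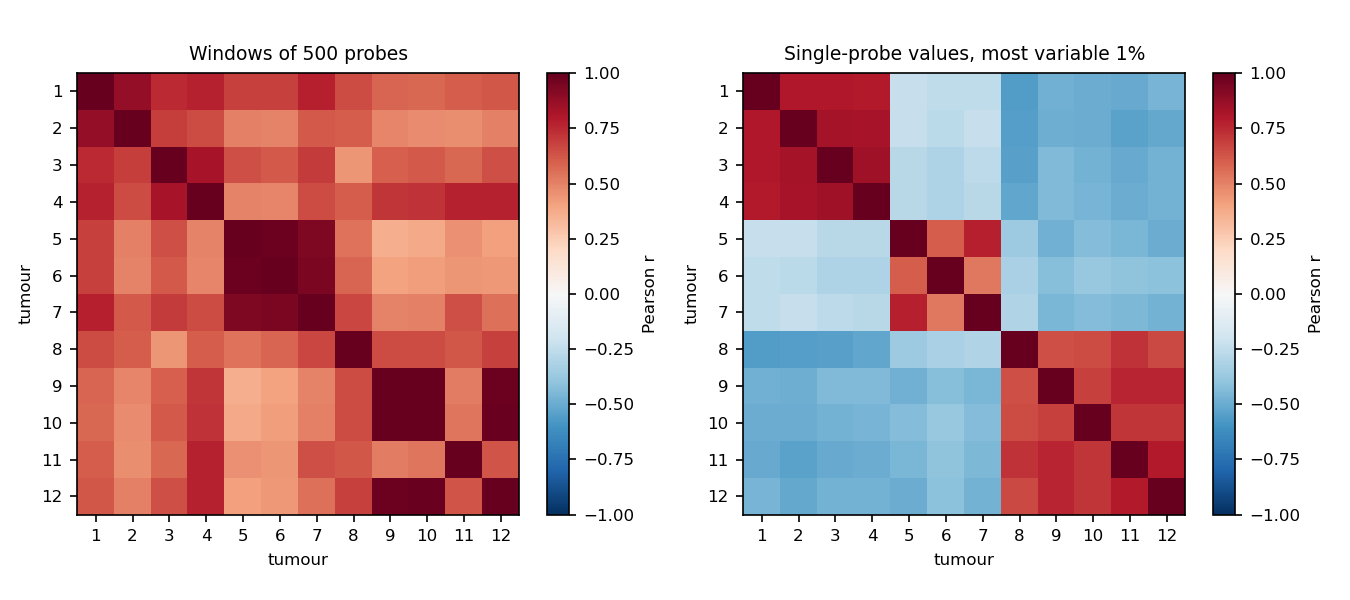
Pearson's r between tumours (both axes) over windows of 500 probes (left) and over the 1626 most variable single probes with the local profile removed (right); colour gives r from -1 to 1. On the right, pairs within tumours 1 to 4, 5 to 7 and 8 to 12 lay at 0.531 or above and all other pairs at -0.227 or below.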

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

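Chosen after seeing the data were the order by probe number, the 500- and 1000-probe windows, the centring on the mode of the running median, natural logs, the averaging of arrays of like profiles, the random block, the single-probe similarity and the counts without tumours 4 and 11. The 4 named probes, 5 regions and 4 further lower blocks (chosen after seeing the data) kept their sign and their side of the threshold in all 228 alternative values run for them. Many of these outcomes were fixed by the choice of items. The probes were picked as the most extreme. All regions and blocks but region 2 had 1 sign in every tumour, so leaving 1 tumour out keeps their sign-flip p at the smallest possible. With 1 tumour left out, probes numbered 21189 to 23651 higher and 17773 to 19375 lower, and windows 83 to 89 higher and 82 to 89 lower. Without tumours 4 and 11, 24529 probes were higher and 20118 lower, 82 windows higher and 84 lower, and 9305 and 2758 probes in recurrent gains and losses, and the median share gained and lost was 11.1% and 1.55%. The random block gave 22403 and 18423 probes.

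Called probes numbered 45125 higher and 42986 lower at a size of 0.1, 9768 and 6812 at 0.3, 7721 and 6256 with treat, 50557 and 49661 if read as log10, and 35498 and 32167 as natural logs. Windows of 1000 probes gave 41 higher and 43 lower of 162. Lower windows numbered 47 without centring, 54 with the running-median mode and 56 with like profiles averaged, which leaves 8 values. Probes in recurrent gains and losses numbered 21804 and 6459 at 0.1, 1112 and 956 at 0.3, 4070 and 1836 with mode centring, 2887 and 1480 with the running-median mode, 156 and 860 without the common component, 1626 and 823 with like profiles averaged, 18299 and 9844 as log10, and 16561 and 6000 as natural logs. Recurrent gains alone also moved, to 4577 and 3542 at penalties of 2 and 8 and to 4928 with a running median of 21 probes. The median share gained and lost was 19.3% and 16.4% at 0.1, 27.9% and 29.9% as log10, and 17.8% and 13.2% as natural logs, and fell from 6.28% and 0.979% to 0.669% and 0.376% at 0.3 and to 0.166% and 0.195% without the common component, changes below the SD over tumours but large as ratios. The median share lost also rose, to 5.2% with a running median of 21 probes and to 2.27% at a penalty of 2. The gained share of tumour 10 fell from 16.9% to 0.0794% without the common component. As natural logs the very high probes had a mean of 6.58. Thresholds and log bases move counts by construction; for centring, penalty and running median the cause was not tested. Highest, lowest and median r were 0.834, 0.469 and 0.587 with Spearman's coefficient and 0.848, -0.557 and -0.344 over the single-probe values, whose probe means are removed, which allows negative r.

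Not run were the gene median, the minimum of 3 probes per gene, the GC correction, and the alternatives for gene lists, Kmt5a and sex chromosomes, all of which need probe positions or genes. No paired analysis was possible because there is 1 group. Signal over background was not analysed here.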

Other observations

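Of the tests in this part, those of slides of 4 arrays, both tests of the very high probes, the test of the reference DNA and the test of a diluted gain in region 4 were chosen after the values they use, or values close to them, were seen; the others were written before. The edge test of region 4 was later widened from tumour 6 to the other 11 tumours.

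Short runs of variable probes gave other places where tumours differed as a set of arrays. At 7 probes at 31.8% of run 3, tumours 1 to 4 had medians of -0.901, -1.08, -0.816 and -0.845, and the other 8 tumours lay between -0.173 and -0.00169. At 6 probes at 68% of run 2, tumours 5, 6 and 7 had -0.129, -0.327 and -0.052, and the other 9 lay between 0.596 and 0.867. These places were picked because they vary, and no test was made.

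The split of single-probe values into 3 sets was weighed against technical sources. At 207 variable probes every array's running median lay within 0.1 of 0. There the lowest r within sets still exceeded the highest r between sets by 0.609. These probes are among the 1626 that gave the sets, and the running median of 51 probes had already been removed from their values. The difference therefore argues against leakage from broad copy-number changes at these probes only. Among 1040 variable probes at least 20 probes apart, the same set stood apart at neighbouring probes in 56.4% of cases, against a mean of 42.9% and a highest value of 46.9% in 1000 shuffles, which argues against array effects that act on probes regardless of their place as the whole source. Slides of 4 arrays in numerical order would put array 8 with arrays 5 to 7. The 809 variable probes of run 2 alone gave the same 3 sets, and at the 817 variable probes of runs 1 and 3 the lowest r of array 8 with arrays 9 to 12, 0.577, exceeded its highest r with arrays 5 to 7, -0.244, by 0.821 (bootstrap SE 0.088), which argues against such slides as the source of the sets. Over all 162551 probes, array 8 had r of 0.271, 0.238, 0.153 and -0.0485 with arrays 9 to 12, and of -0.289, -0.168 and -0.0467 with arrays 5 to 7. Without the variable probes these were 0.089, 0.0114, -0.118 and -0.321, and -0.25, -0.0547 and 0.101, so effects of slides or batches on the other probes stay open. A candidate explanation that stays open is a germline genotype shared within a set, from 1 animal or from close relatives on the mixed C57BL6/CBA background; it was not tested directly, and other batches stay open too.

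The very high probes were weighed as an amplification in tumour cells diluted by other cells. For the 4 tumours whose windows correlated at 0.9 or more with those of tumour 6 or tumour 9, the observed median minus the value predicted from the scale had a median of 0.419 (bootstrap SE 0.115). It was 0.381 in tumour 5, 1.02 in tumour 7, 0.458 in tumour 12 and -0.211 in tumour 10 (SE of 0.146 to 0.167). The nearly flat tumours 4 and 11, whose windows fit those of a partner less well (r of 0.824 and 0.483), had medians of 5.26 and 4.72. Of the 4 tumours with close partners, only tumour 7 lies above its prediction by more than the margin of the test. Tumours 5 and 12 lie above theirs by less than that margin, and tumour 10 lies below its own, within 2 SE. The SE covers probe noise alone and close partners exist for 4 tumours only, so a diluted amplification cannot be told apart from other sources here. An inherited or reference-side difference fixed within each set was weighed as well. The gap between tumours 5 to 7 and the nearest other tumour exceeded the widest range within a set by 0.076. That is less than the SE of a tumour's median, so such a difference cannot be told apart from other differences between arrays. A variant of the shared reference alone would give the same value on every array, so this gap cannot test it.

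Region 4, higher in every tumour, was weighed against a variant of the reference DNA, which would give the same value on every array; its median window instead ranged over 0.544, from 0.0863 in tumour 4 to 0.63 in tumour 6, which argues against the reference as the whole source. A gradual wave along the genome was argued against by its edges: in tumour 6 at least 0.883 of the change over 500 probes on either side lay within 50 probes, at 6 edges, and over the mean of the other 11 tumours, at the edges placed in tumour 6, at least 0.827. A gain present in tumour cells and diluted to a different degree in tumours 5 to 7 stays open as a hypothesis: predicted from tumour 6 and the scale of the other windows, the region differed by 0.0885 in tumour 5 and by -0.0127 in tumour 7. In tumours 10 and 12, predicted from tumour 9, it differed by 0.0264 and 0.0261. The other 4 predictions rest on looser fits (r of 0.483 to 0.882), and the region differed from them by 0.0922 in tumour 1, 0.0745 in tumour 11, 0.069 in tumour 8 and -0.0115 in tumour 4. All 8 differences lie within the tolerance of 0.1, which says little for these 4 tumours and tumours 10 and 12, where the region itself is below 0.2. In tumour 5 the difference of 0.0885 is larger than the residual SD of the windows around the fit, 0.0345. It is also larger than the SE of the region over its windows in tumour 5, 0.028. The tolerance is thus wide for tumour 5 as well. The reference as part of the source was not tested and stays open.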
